A study of Mus musculus with 4 samples.

How the data were processed

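RNA from whole kidneys of mouse embryos was taken through poly(A) selection and a DNA library kit, per the labels' protocols, which do not describe the libraries as stranded. The FPKM values (fragments scaled to transcript length and to the mapped fragments of the library, 1 value per gene row with the bounds of an interval) were computed by the authors, and the deposited tables hold 1 library each. Per the submitters' processing notes the tools were TopHat2 2.0.11, Bowtie 1.0.0, SAMtools 0.1.19 and Cufflinks 2.1.1, with genome build mm9; the annotation and options are not given in the sources used here. Gene numbers that carry a prefix of their own in each table, and rows without a gene name, show that loci were assembled separately in each library, so that a gene's boundaries and FPKM can move with the assembly. The tables held between 26000 and 26488 rows, and rows without a gene name held 48.9% and 45.0% of the FPKM sum in control replicates 1 and 2 and 48.8% and 41.9% in mutant replicates 1 and 2. Loci under 200 bp held from 89.1% (mutant replicate 2) to 93.5% (mutant replicate 1) of this unnamed FPKM, so these shares rest mostly on short loci. In the table of control replicate 1 the interval was symmetric about the FPKM, within 1% of it, in all 16595 rows with a lower bound above 0, whereas in the others it was not in 45.4% to 47.4% of such rows. Why this table differs was not tested.

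The FPKM tables contain no read totals. Among genes below an FPKM of 0.1 in a pair of libraries, the most frequent log2 ratio was 0.00 between the control libraries and between control replicate 1 and mutant replicate 1, and 0.20 for each of the other libraries over mutant replicate 2, as if mutant replicate 2 held about 1.15 times as many mapped fragments. Absolute depth stayed unknown, so no interval from counts is given.

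Rows were joined by gene symbol. Of 23852 names in any table, 22761 were in all 4, and the rest were left out, as were 99 genes with a row not marked OK; FPKM was summed over rows that share a name (158 genes), and 402 joint names of several genes were kept as they stood. Genes with an FPKM of at least 1 in at least 2 libraries were tested, on log2(FPKM + 1) and without further scaling, with limma 3.58.1 in R 4.3.3 (lmFit, eBayes with a mean-variance trend, group as the single term), with Benjamini-Hochberg adjustment and a threshold of 0.05. Log2 changes are on the log2(FPKM + 1) scale, which understates the change of genes at low levels. Percentages of control are ratios of mean FPKM. Some genes are listed at an exact 0 that can be a failed estimate, so these are given per library and without a fold.

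Before the data were examined, 32 gene lists were fixed from textbook knowledge of kidney cell types, proximal tubule functions, other cells that dissection could bring along and cell states; 2 of them, sex-linked and housekeeping genes, are given as values. The 29 other lists with at least 3 tested members were tested with camera at a preset inter-gene correlation of 0.01, adjusted over lists, with camera at an estimated correlation and fry beside it. Fry tests whether a list's genes move on balance one way and does not compare them with other genes. The rule for named genes, fixed at the same time, took Hnf4a; the 10 largest falls and rises past the threshold whose groups do not overlap, leaving out unnamed gene models, microRNAs and small nucleolar RNAs, or all if fewer passed; from each list up to 4 members past the threshold with the largest change, or else the 2 with the highest mean level, as values; every detected sex-linked gene and the range of the housekeeping genes. If no gene had passed in a direction, the 5 largest changes without overlap at an unadjusted p under 0.05 would have been given as values. The rule did not say over which genes list members were to be adjusted, and adjustment over the list alone was chosen after the values were seen. Some genes that the rule names are not reported here, though they were counted in their lists.

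The 15 alternatives fixed beforehand changed the pseudocount, the filter, the scaling, the variance model, the treatment of symbols with several rows, the threshold, the replicate number as a block and each library left out in turn; 3 more, without small RNA genes, genes at 0 or joint names, were added after seeing the data. With 1 library left in a group, its spread was taken to be that of the other group.

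The comparison was tested on simulated data with the means and spreads of the real libraries, in 13164 genes. It recovered 38 of 100 genes changed by 1 on the log2 scale and 81 of 100 changed by 2, with 6 unchanged genes past the threshold. The changed genes were drawn from those with a mean level above about 5 FPKM. Noise was independent between genes and libraries, and zeros by group or loci that differ between assemblies were not simulated. The recovery and the number of false calls need not hold for lower levels or for such genes. No genome was used here, and coordinates are those of the tables, in mm9, with starts counted from 1.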

Results

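Whole kidneys of mouse embryos at E18.5 were profiled by RNA sequencing to ask which genes depend on Hnf4a, a nuclear receptor of the developing proximal tubule, the segment that recovers sugars, amino acids, salts and proteins from the filtrate. Six2GFPcre, a Cre recombinase active in nephron progenitors and so inherited by the tubule cells they form, was used to remove the conditional gene. The 2 control libraries came from embryos with 1 conditional Hnf4a allele, and the 2 mutant libraries from embryos in which both alleles were conditional. Both groups carried Six2GFPcre, so the controls could lose 1 copy of Hnf4a in these cells and are not intact. Groups were taken from the labels, which do not name the animals, so p-values measure the spread between these libraries only. The tables gave between 13552 and 13646 named genes at an FPKM of 1 or more per library and no read totals, so the absolute depth is unknown. Replicate 1 of each group carried Y-linked transcripts (Ddx3y at 27.7 FPKM in the control and 26.4 in the mutant library, Eif2s3y at 40.7 and 45.7, Kdm5d at 8.37 and 11.2, Uty at 7.93 and 10.4) and almost no Xist (0.0789 and 0.131). Replicate 2 of each group had Xist at 81.0 and 74.0 FPKM, Ddx3y at 0.0301 and 0.0265, Uty at 0 and 0.0234, and the other Y-linked transcripts at 0, so each group held 1 library of either pattern.

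The level of Hnf4a itself differed by less than the spread between libraries. Hnf4a (mm9 chromosome 2, 163372850 to 163398643) was at 89.3 and 84.6 FPKM in the control libraries and at 87.1 and 78.5 in the mutant libraries. The log2 change was -0.07 (SE 0.08), with an adjusted p of 0.83. The value covers the whole gene, and the part removed from the conditional allele is not given in the sources used here. It therefore does not check the genotype labels.

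The genes that fell in the mutant kidneys included brush border and metabolic genes of the proximal tubule. Vil1, which encodes the microvillar actin-bundling protein villin, averaged 26.4 ± 0.742 FPKM in control and 6.49 ± 0.627 in mutant libraries (SD, n = 2 per group here and below), a log2 change of -1.87 (SE 0.12). Mep1b, a subunit of the brush border protease meprin, fell from 36.1 ± 0.478 to 10.7 ± 0.867 FPKM. Aadat, an aminotransferase of the kynurenine pathway, fell from 139 ± 11.6 to 48.4 ± 2.48 FPKM, and Qprt, which makes a precursor of NAD from quinolinate, fell from 40.5 ± 0.304 to 15.1 ± 0.875 FPKM. Fmo1, a flavin-containing monooxygenase, fell from 43.7 ± 2.11 to 16.1 ± 0.252 FPKM. Dimt1, an rRNA methyltransferase, fell from 50.2 ± 3.76 to 10.9 ± 1.35 FPKM, and Atp6v1f, a subunit of the vacuolar proton pump, fell from 325 ± 12.5 to 145 ± 0.046 FPKM.

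Of 13287 genes tested with limma on log2(FPKM + 1), 21 passed an adjusted p under 0.05, with 6 higher and 15 lower in the mutant libraries. The same fit called 17 genes when the libraries were split by replicate number, which also separates the Y-linked and Xist patterns, and 7 when they were split crosswise. At an unadjusted p under 0.05, 355 genes were higher and 607 lower, where chance gives about 332 each way. In simulated data the same fit gave 5.79% of unchanged genes such a p, somewhat above the nominal share. The 355 higher genes are therefore no clear excess. The 962 genes of either direction compare with 402 in the split by replicate number and 299 in the crosswise split. In both of these splits each group held 1 control and 1 mutant library, so differences by genotype widen the spread and lower the counts. Their counts are therefore not a baseline for chance. The groups did not overlap in 39.8% of tested genes, against 33.3% by chance. Of the 21 genes, 10 were listed at 0 in both libraries of a group, and 7 were small RNA genes, a class that poly(A) selection and gene-level FPKM measure poorly. Snord35b, for example, was listed at 790 and 778 FPKM in the control libraries and at 0 in both mutant libraries. With genes at 0 in any library left out, 10 genes passed, 1 higher and 9 lower. With the replicate number as a block, 6 genes passed, 3 higher and 3 lower. Vil1, Mep1b, Aadat, Qprt, Fmo1, Dimt1 and Atp6v1f did not pass with that block. Without control replicate 1 or without control replicate 2, limma called 0 genes, with 290 higher and 739 lower, and 1169 higher and 1124 lower, at an unadjusted p under 0.05.

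Other called genes named by the rule, except Ccpg1os, had overlapping or altered loci or were listed at 0 in a group. Emx2os fell from 25.7 ± 1.82 to 4.39 ± 0.388 FPKM, and Emx2, which its locus overlaps, was at 43.6 and 45.7 against 43.6 and 43.1 FPKM. Ndufa13, whose locus overlaps Tssk6, rose from 50.7 ± 3.39 to 161 ± 2.63 FPKM. The Ndufa13 locus ended at position 72426457 of mm9 chromosome 8 in both control libraries and at 72426902 and 72426903 in the mutant libraries. Fam120aos, which overlaps Fam120a, was listed at 0 in both control libraries and at 31.2 and 29.1 FPKM in the mutant libraries. Tmem191c was listed at 10.5 and 10.7 FPKM in control libraries and at 0 in both mutant libraries, and the spliceosomal small RNA Rnu11 at 0 in both control libraries and at 217 and 93.8 FPKM in the mutant libraries. The sources do not state that strand was used, so reads of overlapping genes on opposite strands cannot be assigned with certainty. Other falls of genes named by the rule also had loci that overlap another named gene, on strands not checked here. They were Vil1 (Usp37), Slc7a7 (Oxa1l), Slc3a1 (Prepl), Slc26a1 (Idua), Slc5a10 (Fam83g), Slc34a1 (Pfn3), Glyctk (Mir135a-1), Pcx (Lrfn4) and Acot4 (Acot1 and Acot3). Their reads cannot be assigned with certainty either. Loci also moved in single libraries for Dimt1 and Qprt. The Dimt1 locus ended at 107750623 in mutant replicate 2 and at 107750304 in the other libraries. The Qprt locus started at 134250710 in control replicate 1 and at 134251284 in the other libraries. Falls of genes that the rule does not name were not checked for overlap. Ccpg1os, named as an opposite-strand transcript of Ccpg1, overlapped no other named locus and rose from 13.9 ± 0.803 to 37.2 ± 1.22 FPKM.

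**Figure D1:**
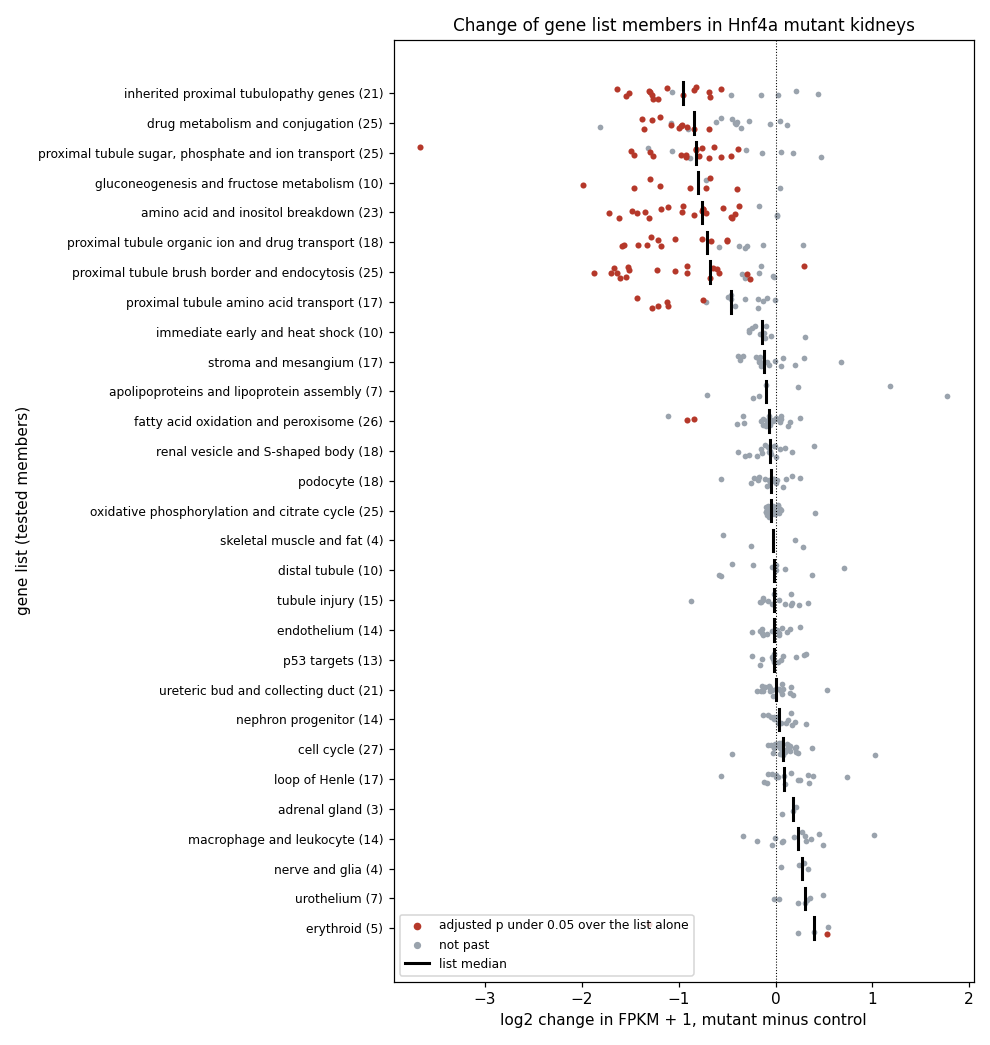
Log2 change of FPKM + 1 (mutant minus control, x axis) of every tested member of 29 gene lists (y axis, number of tested members in brackets), each point 1 gene. Red points passed an adjusted p under 0.05 over the list alone, and black bars are list medians; the bars of the 8 lists of proximal tubule functions and disease genes lie between -0.46 and -0.95, and the other 21 between -0.14 and 0.39.

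Transporters of the proximal tubule fell as groups. Among carriers of amino acids, 6 of 17 tested members fell, adjusted over the list alone, and 0 over all genes tested. They included Slc6a13 (33.9% of the control mean), Slc7a9 (37.3%) and Slc3a1 (46.0%), the last being partners in cystine uptake, and the basolateral carrier subunit Slc7a7 (41.1%). All 17 had negative changes, with a median of -0.46 (camera adjusted p = 2.91e-10; adjusted p = 0.325 with an estimated correlation). Without control replicate 1 the median was -0.26. Among carriers and channels of sugars, phosphate and ions, 17 of 25 members fell over the list alone and 0 over all genes, with a median of -0.82 (camera adjusted p = 4.25e-18; adjusted p = 0.318 with an estimated correlation). Slc34a1, the main sodium-phosphate cotransporter, fell from 106 ± 17.8 to 42.5 ± 3.96 FPKM, Slc13a3 fell to 29.4% and Slc5a10 to 30% of control. Slc26a1, whose locus overlaps Idua, was at 17.4 and 7.77 FPKM in control libraries and listed at 0 in both mutant libraries. Without mutant replicate 1 or without mutant replicate 2, 10 members of this list fell.

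Carriers of organic ions and drugs had 12 of 18 members lower over the list alone and 0 over all genes, with a median of -0.71 (camera adjusted p = 1.88e-15; adjusted p = 0.318 with an estimated correlation). Slc22a6, the organic anion transporter OAT1, fell from 37.2 ± 14.3 to 11.5 ± 1.45 FPKM, Slc17a3 to 32.8% and the export pump Abcc2 to 24.3% of control.

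In the list of brush border and endocytosis genes, 18 of 25 members fell and 1 rose over the list alone, and 2 fell over all genes, Vil1 and Mep1b. The median was -0.68 (camera adjusted p = 2.43e-20; adjusted p = 0.294 with an estimated correlation). The protein uptake receptors Lrp2 (megalin) and Cubn (cubilin) fell from 46.7 ± 2.51 to 15.8 ± 1.68 and from 15.2 ± 2.37 to 4.56 ± 0.437 FPKM, and their partner Amn fell from 57.8 ± 6.81 to 17.9 ± 2.88 FPKM. Cdhr2, a protocadherin of microvillus tips, fell to 22.8% of control. Members of the same list did not all fall. Dpp4, a brush border peptidase chosen after its values were seen, was the member that rose, from 44.7 ± 2.26 to 55.1 ± 3.01 FPKM, with a list-alone adjusted p of 0.030 and 0.51 over all genes. The peptidase Mme (50.6 ± 1.33 against 50.2 ± 2.89 FPKM), also chosen after its values were seen, differed by less than the spread between libraries. No member of the list passed as higher without control replicate 1 and without either mutant replicate.

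**Figure D2:**
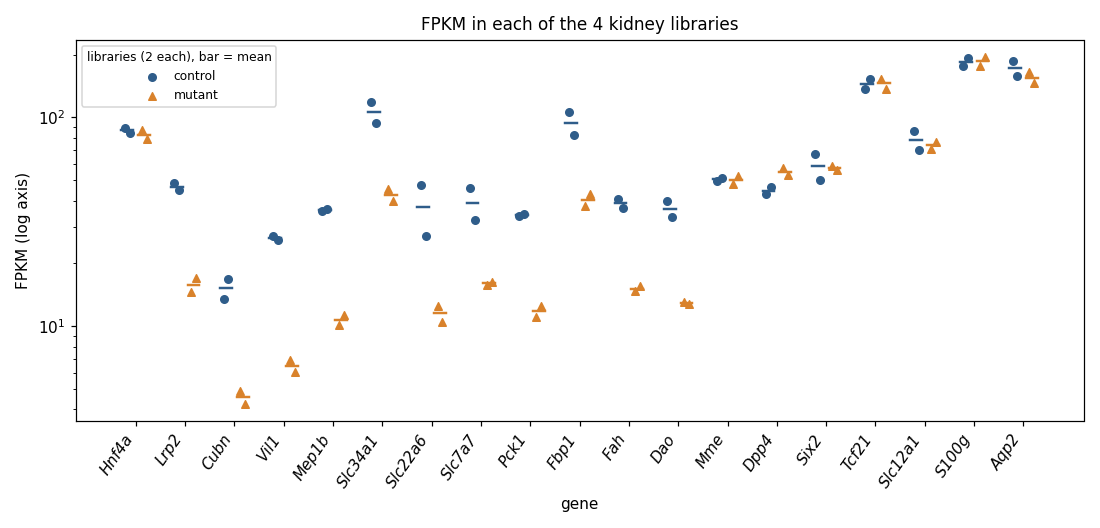
FPKM (y axis, log scale) of 19 genes in each of the 2 control libraries (circles) and 2 mutant libraries (triangles), with a bar at each group mean. From Lrp2 to Dao both mutant libraries lie below both control libraries (Lrp2 at 14.6 and 17 against 48.5 and 44.9), while Hnf4a and Mme and the genes of other kidney cells from Six2 to Aqp2 have means in the mutant libraries between 90.0% and 101% of the control means.

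Metabolic genes of the proximal tubule fell as well. The list of amino acid and inositol breakdown had 20 of 23 members lower over the list alone and 0 over all genes, with a median of -0.76 (camera adjusted p = 1.17e-21; adjusted p = 0.318 with an estimated correlation). Dao, which oxidises D-amino acids, fell from 36.5 ± 4.36 to 12.9 ± 0.237 FPKM, Agxt2 to 27.6% and the tyrosine pathway gene Hgd to 30.8% of control. Haao, an enzyme of quinolinate synthesis, fell from 3.11 ± 0.247 to 0.25 ± 0.026 FPKM. Fewer members of this list fell without control replicate 1 (13), without mutant replicate 1 (9) and without mutant replicate 2 (12). Of gluconeogenesis and fructose metabolism genes, 8 of 10 fell over the list alone and 0 over all genes, with a median of -0.80 (camera adjusted p = 2.34e-12; adjusted p = 0.325 with an estimated correlation). Pck1, the cytosolic enzyme that commits carbon to glucose synthesis, fell from 34.1 ± 0.657 to 11.8 ± 1.04 FPKM, Fbp1 from 94.4 ± 17.5 to 40.4 ± 3.68, and Pcx to 39.2% of control. Glyctk fell from 34.1 and 15.6 FPKM in the control libraries to 4.68 and 5.47 in the mutant libraries, so the size of its fall depends on control replicate 1.

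Drug metabolism and conjugation genes had 11 of 25 members lower over the list alone and 1, Fmo1, over all genes, with a median of -0.84 (camera adjusted p = 4.81e-17; adjusted p = 0.294 with an estimated correlation). Glyat, which conjugates acyl groups to glycine, fell from 33.1 ± 9.56 to 12.0 ± 0.376 FPKM, Acsm1 to 35.7% and Akr1c21 to 37.0% of control. This was the single list past the threshold with fry (adjusted p = 0.019), and the camera calls of all 11 lists were lost with an estimated correlation.

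The lists of transport, brush border, glucose, drug and amino acid metabolism above held 143 different tested genes, of which 133 had negative changes. Adjusted over these genes alone, 89 fell and 1 rose. A list of genes mutated in inherited proximal tubulopathies shared 18 of its 21 members with other lists, so it is not independent of them. In it, 15 of 21 members fell over the list alone and 0 over all genes, with a median of -0.95 (camera adjusted p = 2.34e-18; adjusted p = 0.318 with an estimated correlation). By log2 change, the members with the largest falls were Amn, Cubn, Lrp2 and Fah. The last, an enzyme of tyrosine breakdown, fell from 39.0 ± 2.70 to 15.1 ± 0.567 FPKM.

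Mitochondrial and fatty acid genes showed smaller differences. Among fatty acid oxidation and peroxisome genes, 2 of 26 members fell over the list alone and 0 over all genes, Acot4 from 6.91 ± 0.152 to 3.20 ± 0.332 FPKM and Ehhadh from 9.88 ± 0.499 to 5.06 ± 0.145. Leaving out any 1 of the 4 libraries left 0 such members. The list's median was -0.07 (camera adjusted p = 0.0048; adjusted p = 0.50 with an estimated correlation), and its camera call was lost without control replicate 2 (adjusted p = 0.105) and without mutant replicate 1 (0.087). Oxidative phosphorylation and citrate cycle genes had a median of -0.04 (camera adjusted p = 0.178), with Cox4i1 at 249 ± 6.80 against 232 ± 15.2 FPKM and Cox8a at 240 ± 6.15 against 228 ± 12.0. That list passed without control replicate 1 (0.014) and without mutant replicate 1 (0.035). Apolipoprotein genes had a negative median of -0.09, a positive mean of 0.28 and a camera adjusted p of 0.746, with Apoe at 131 ± 2.48 against 117 ± 2.17 FPKM and Pltp at 30.9 ± 1.36 against 28.9 ± 0.976.

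None of the tested members of the lists for other nephron segments passed over the list alone or over all genes, and none of these lists passed with camera. Nephron progenitor genes had a median of 0.04 (adjusted p = 0.421), with Six2 at 58.5 ± 12.0 against 57.2 ± 1.78 FPKM and Crym at 55.8 ± 4.42 against 60.0 ± 0.854. Without control replicate 1 the progenitor list passed as higher, with a median of 0.19 (adjusted p = 8.06e-05). Renal vesicle and S-shaped body genes had a median of -0.06 (adjusted p = 0.142), with Ccnd1 at 97.3 ± 2.5 against 96.0 ± 6.89 FPKM and Sox4 at 73.6 ± 8.60 against 69.5 ± 4.69. Podocyte genes had a median of -0.05 (adjusted p = 0.178), with Tcf21 at 145 ± 10.7 against 146 ± 11.3 FPKM and Cdkn1c at 205 ± 39.9 against 175 ± 11.7. Genes of the loop of Henle had a median of 0.09 (adjusted p = 0.222), with Slc12a1 at 78.2 ± 11.6 against 73.5 ± 3.80 FPKM and Sostdc1 at 82.2 ± 9.22 against 87.8 ± 0.047. Distal tubule genes had a median of -0.02 (adjusted p = 0.598), with S100g at 184 ± 11.9 against 185 ± 13.2 FPKM and Calb1 at 54.2 ± 7.51 against 91.9 ± 35.1. Genes of the ureteric bud and collecting duct had a median of 0.0004 and a camera direction of lower (adjusted p = 0.746), with Aqp2 at 173 ± 20.4 against 155 ± 13.3 FPKM.

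Other cell types of the tissue, or cells that dissection could bring along, also gave no list past the threshold. The camera adjusted p was 0.086 for stroma and mesangium (median -0.12; Penk at 152 ± 0.708 against 135 ± 1.01 FPKM and Col3a1 at 131 ± 10.5 against 117 ± 11.3), 0.421 for endothelium (median -0.01; Egfl7 at 89.5 ± 11 against 96.8 ± 9.51 and Cldn5 at 77.9 ± 1.16 against 78.6 ± 1.35) and 0.084 for macrophages and leukocytes (median 0.23; C1qc at 21.3 ± 1.20 against 26.5 ± 3.79 and Tyrobp at 26.4 ± 5.72 against 20.5 ± 1.61). The stroma list passed as lower (adjusted p = 0.0037) and the macrophage list as higher (0.0050) without mutant replicate 1. The urothelium list had a median of 0.30 (adjusted p = 0.178), with Upk3a at 33.1 ± 0.065 against 42.2 ± 8.05 FPKM and Upk2 at 18.7 ± 3.82 against 24.7 ± 12.6, and passed as higher without mutant replicate 2 (median 0.74, adjusted p = 6.55e-06). Without mutant replicate 1 its median was -0.09, short of the threshold. Of 5 tested erythroid genes, Alas2 was higher (18.6 ± 2.32 against 27.1 ± 0.756 FPKM) and Hbb-y lower (4.25 ± 0.417 against 1.19 ± 0.745) over the list alone, and 0 passed over all genes; the list median was 0.39 and its mean 0.08 (adjusted p = 0.448). Without control replicate 1 or without mutant replicate 1, neither erythroid gene passed. The adjusted p was 0.598 for the adrenal list (3 tested genes; Akr1b7 at 19.6 ± 4.72 against 22.5 ± 5.83 FPKM and Pnmt at 1.19 ± 1.13 against 1.43 ± 0.805), 0.598 for skeletal muscle and fat (4 tested genes; Tnnt3 at 5.15 ± 0.971 against 4.16 ± 0.643 and Actc1 at 2.0 ± 0.746 against 2.79 ± 2.40) and 0.20 for nerve and glia (4 tested genes; Stmn2 at 4.12 ± 0.965 against 5.35 ± 1.66). The gonad and Wolffian duct list had too few tested genes for a set test, with Crisp1 at 12.5 ± 2.73 against 10.3 ± 1.96 FPKM and Dhh at 1.37 ± 0.279 against 1.66 ± 0.503.

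Lists of cell states moved little. Cell cycle genes passed as higher with a median of 0.08 (camera adjusted p = 0.021; adjusted p = 0.50 with an estimated correlation) and 0 members past the threshold, with Pcna at 111 ± 7.43 against 114 ± 4.95 FPKM and Mcm7 at 64.0 ± 1.25 against 66.6 ± 0.843. Immediate early and heat shock genes passed as lower with a median of -0.14 (camera adjusted p = 0.046; adjusted p = 0.533 with an estimated correlation) and 0 members past the threshold, with Jun at 46.8 ± 1.78 against 39.4 ± 0.647 FPKM and Ier2 at 52.0 ± 0.521 against 50.5 ± 1.43. The cell cycle call was lost without any 1 of the 4 libraries (adjusted p from 0.054 to 0.087), and the immediate early call without control replicate 2 (0.346), mutant replicate 1 (0.108) or mutant replicate 2 (0.174). Tubule injury genes (median -0.01, adjusted p = 0.598; Anxa2 at 149 ± 10.3 against 152 ± 13.0 FPKM and Vim at 153 ± 1.37 against 145 ± 8.62) and p53 targets (median -0.01 with a camera direction of higher, adjusted p = 0.988; Bax at 93.5 ± 0.0067 against 95 ± 0.558 FPKM and Cdkn1a at 57.9 ± 4.23 against 51.5 ± 1.25) did not pass. Log2 changes of 11 housekeeping genes ranged from -0.16 to 0.30.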

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

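Rows without a gene name were in no comparison, and the count of them given here, with its limits, was chosen after the other results were seen. Of 601 unnamed loci of at least 200 bp found by overlap in all 4 libraries, 10 were at least 2 times higher in both mutant libraries than in both control libraries at an FPKM of at least 5, and 20 were lower by the same measure, 30 either way, against 15 and 21 either way when the libraries were split by replicate number or crosswise. One of the 10, on mm9 chromosome 9 from 96916382 to 96922574, lies within the locus of Spsb4 (50.7 and 45.7 FPKM in the control and 34.9 and 34.3 in the mutant libraries). It was at 6.27 and 6.33 FPKM in the control and 27.4 and 25.2 in the mutant libraries, and was singled out after its values were seen.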

How the results depend on the processing

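The settings without small RNA genes, without genes at 0 and without joint names were chosen after seeing the data. All 8 lists of proximal tubule functions and disease genes stayed lower and past the threshold in all 18 alternatives, with camera adjusted p of at most 3.53e-06 and medians between -1.12 and -0.26. The number of lists past the threshold (11) stayed within 1.5 times under every alternative, and Hnf4a stayed short of the threshold, with log2 changes from -0.14 to 0.0025 when 1 library was left out. No called gene or list reversed its direction. None of the 18 alternatives changed camera's preset inter-gene correlation of 0.01, so the stability of the list calls was seen under that preset only. With an estimated correlation in the main setting, all 11 list calls were lost, those of the 8 lists included. The lowest adjusted p of camera over the 29 lists was then 0.294. For the drug metabolism list the estimated correlation was -0.035, below the preset, and its adjusted p still rose from 4.81e-17 to 0.294. The size of the correlation alone therefore does not account for the loss, whose cause was not tested. Within the 18 alternatives, the number of genes changed (21, with 6 higher and 15 lower) moved most. It was 10 (6 lower) without a filter, 33 (26 lower) at an FPKM minimum of 5, 11 (7 lower) without a mean-variance trend, 37 (29 lower) with a robust variance prior and 79 (13 higher, 66 lower) at an adjusted p under 0.10. It was 11 (2 higher, 9 lower) without small RNA genes and 10 (1 higher, 9 lower) without genes at 0. A filter changes how many genes share the adjustment, and the cause of the other shifts was not tested. With 1 library left out it ranged from 0 to 14 (0 to 5 higher, 0 to 9 lower), and was 0 without either control replicate and 12 without mutant replicate 1, with fewer residual degrees of freedom. The labels name no litter and do not state that replicate numbers pair libraries. Same-numbered libraries did share a pattern, since replicate 1 of each group was the Y-positive library. Deviations of same-numbered libraries correlated at 0.146 over genes, so a shared structure by replicate number stays open. With the replicate block, which leaves log2 changes as they were and takes a residual degree of freedom, 6 genes passed (3 higher, 3 lower). Vil1, Mep1b, Aadat, Qprt, Fmo1, Dimt1 and Atp6v1f no longer passed over all genes (adjusted p from 0.090 to 0.171), while the urothelium list passed as higher (0.037) and the immediate early list no longer passed (0.072). Without a trend, the cell cycle and immediate early lists no longer passed (both 0.052), and at an FPKM minimum of 5 the apolipoprotein list passed as lower (0.048). At an adjusted p under 0.10, the stroma and macrophage lists passed. Over named genes, 43 of 1247 combinations with the alternatives that keep all libraries lost a call and 0 gained one; with 1 library left out, 68 of 360 lost and 1 gained one. Depth is unknown, so what it limits cannot be given.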

Other observations

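All lists and tests of explanations in this part were chosen after the results were seen, so none is independent evidence of a direction. The p-values of the lists added here were adjusted over these 4 lists alone, and not over the 29 lists fixed beforehand, so they cannot be compared with those of the 29. The named falls Aadat and Qprt belong to kynurenine and NAD metabolism. Of 11 tested genes of that metabolism, 4 were lower over the list alone. They were Aadat (48.4 against 139 FPKM), Haao (0.25 against 3.11), Acmsd (4.59 against 11.4) and Qprt (15.1 against 40.5). Of these, Aadat and Qprt passed over all genes. The list had a median of -0.35 (camera adjusted p = 0.00014; adjusted p = 0.141 with an estimated correlation). The other 7 members did not pass, among them Afmid (5.0 against 5.17 FPKM) and Kynu (3.24 against 3.17) of the kynurenine steps. Their log2 changes ranged from -0.60 (Nmnat3, 9.73 against 15.4 FPKM) to 0.47 (Nmnat1, 13.3 against 9.45). Of 4 tested urea cycle and arginine synthesis genes, Ass1 (63.5 against 107 FPKM) and Asl (39.0 against 56.2), which together make arginine from citrulline, were lower over the list alone (camera adjusted p = 0.0018; adjusted p = 0.115 with an estimated correlation).

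The complex that links neighbouring microvilli was lower as a group. All 6 tested members fell over the list alone and 0 over all genes. Cdhr2, Cdhr5, Ush1c and Myo7b are also members of the brush border list above, so this result partly restates that one. Each of the other lists added here also shares members with lists fixed beforehand. The cadherins Cdhr2 and Cdhr5 were at 2.23 against 9.79 and 9.97 against 19.5 FPKM, and their partners Ush1c, Myo7b, Anks4b and Calml4 at 19.2 against 30.6, 0.764 against 2.68, 7.02 against 16 and 72.7 against 120 FPKM (median -0.98, camera adjusted p = 2.27e-09; adjusted p = 0.049 with an estimated correlation). Of 8 genes of the PDZ scaffold under the brush border and its partners, 7 were lower over the list alone (median -0.70, camera adjusted p = 3.02e-11; adjusted p = 0.049 with an estimated correlation), with Pdzd3 at 4.29 against 13.7 and Pdzk1 at 68.5 against 131 FPKM. Slc9a3r2 was at 81.1 against 77.8 FPKM.

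The lower proximal tubule lists were weighed against tissue mixture and cell loss. Tissue from outside the kidney would lower the other kidney cells by about the median of the 7 function lists, -0.75, whereas 128 genes of 8 such lists had a median of -0.015 (quartiles -0.13 and 0.10). A smaller number of mature proximal tubule cells stays open: 32 of 143 members had intervals above the lists' median, but members also expressed in other cells would fall less, and whole kidneys do not separate cell number from level per cell. The level of Hnf4a cannot report the number of cells, because Hnf4a is the gene that the design alters in them. The 4 libraries allow 3 splits, too few for a share under 0.05; the real split gave 11 lists and 1 of the 3 reached that number, while the highest other split gave 6 lists. Members of proximal tubule and metabolism lists past the threshold over their list alone numbered 95 in the real split and 0 in both others, and the largest median of the 7 function lists was 0.84 in size against 0.10 and 0.18. Each group of the other splits held 1 control and 1 mutant library. A gene that differs by genotype then gains spread within the groups and can hardly pass. The counts and medians of these splits therefore cannot decide about chance.

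The calls listed at 0 or at altered loci may reflect how values were estimated in each library. Among tested genes, 29 were at 0 in exactly 2 libraries and at 10 FPKM or more in the others. The zeros followed the groups in 10, the replicate numbers in 14 and the remaining split in 5. Equally likely splits would give 33.3% for the groups (one-sided exact binomial p = 0.517). The split by replicate number held the most, with 1 gene on the Y chromosome, so equal splits may be a poor baseline. The test therefore cannot decide whether the zeros are random with respect to group. Of 11 called genes above 0 in every library, 2, Ndufa13 and Emx2os, had a start or end at least 100 bp apart between the groups, against 2.48% of 13042 other genes (one-sided Fisher exact p = 0.029), consistent with gene models that differ between assemblies. Transcripts whose structure does differ between genotypes would look alike and stay open.

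A hypothesis was that alleles carried along with the conditional Hnf4a locus changed genes near it. Within 20 Mb of Hnf4a, 6.21% of 306 tested genes had an unadjusted p under 0.05, against 7.26% of 12981 elsewhere (one-sided Fisher exact p = 0.790). An excess was not seen, and an effect on single genes stays open. That holds also for Slc13a3 and Pck1, which fell and whose loci lie in this window.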
